A study of Mus musculus with 8 samples.

How the data were processed

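RNA was measured in 8 subcutaneous tumours of MC38 TetOn-CXCL14 cells, 4 from uninduced and 4 from DOX-treated mice. Per the labels' protocols, the mice were 7 weeks old and male, total RNA was purified on columns from 0.1 g of tumour tissue, and libraries were made with an mRNA library kit for Illumina sequencing. A group was taken from each sample's treatment label and a replicate number from its title. The tumours came from different mice, so the p-values measure the spread between animals. Whether the kit kept strand information, and whether strand was used in counting, is not given in the sources used here, so reads of overlapping or antisense genes may not have been separated.

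The authors deposited a table of read counts per gene and a table of FPKM, each with 18251 genes and 1 column per tumour. The submitters' processing notes name HISAT, Bowtie2 and the build GRCm38.p6, without versions or roles; the counting tool, the annotation release and any filter are not given in the sources used here. The values the authors deposited as read counts are expected counts, since only 64.9% of the values are whole within 0.005, so reads shared between similar genes were divided among them by the authors' tool. This makes counts of paralogs and of clustered families uncertain. Besides the genes for which it is said in place, Foxp3, Lag3, Acta2, H2-DMa, H2-DMb1, H2-D1, H2-K1, Lyz2, Cd22 and Eaf2 had a whole count in 0 of 8 libraries, so their levels hold shared reads of unknown share. The FPKM values, deposited by the authors, are read counts scaled to gene length and library size, named FPKM in the file headers, and served only as an alternative. A deposited table of TPM holds 8 columns whose names match no sample label, and these 8 columns were not used. Genes encoded in the mitochondrial genome were not analysed here.

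Expected counts were rounded to whole numbers. The total per tumour was 18877744, 19098594, 18959023 and 18685975 counts for control tumours 1 to 4 and 18970888, 19093414, 19069513 and 19307481 counts for DOX tumours 1 to 4. The spread between tumours, with a common biological coefficient of variation of 14.7%, was estimated across the tested genes. Counts differed between every pair of libraries by more than sampling noise, with a chi-square per degree of freedom between 5.25 and 71.7 over genes with at least 80 counts in all, so no library was treated as a duplicate.

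The main comparison used edgeR 4.0.16 in R 4.3.3: filterByExpr kept 13436 genes, library sizes were scaled by TMM, and the quasi-likelihood F test with robust dispersion was followed by Benjamini-Hochberg adjustment at 0.05, without a fold minimum. The SE of a log2 fold change was taken as its size divided by the square root of F. CPM values are TMM-scaled. For Cxcl14 and Adgrg1 an exact two-sided permutation test of log2(CPM + 1) over all 70 allocations was added. Gene lists, 53 in number, were fixed before the data were examined, as were the main tests, the rule for naming genes and those alternatives not said to have been added later. They cover immune cells, the epithelial-mesenchymal transition, stroma, signalling, metabolism and tissues next to a subcutaneous tumour. The 49 lists with at least 5 tested members were tested with fry of limma 3.58.1 on log2 CPM (prior count 2), with adjustment over the 49. Fry's test asks whether the genes of a list move one way on balance and does not compare the list with other genes. A list score is the mean log2 CPM of its tested members in a tumour. Coordinates are those of NCBI's annotation of GRCm38.p6, matched by gene symbol; 47 symbols of the table had no match there.

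The rule for named genes took Cxcl14, then up to 10 of the largest rises and of the largest falls among genes past the threshold whose groups did not overlap and whose mean log2 CPM was above 0, leaving out unnamed gene models. Where none qualified, the 5 with the smallest p in that direction were taken. From each list described, up to 4 tested members with the smallest p were eligible. Only Adgrg1 qualified as a rise and none as a fall. Genes outside this rule are said to be chosen after their values were seen.

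On simulated counts with the means, library sizes and dispersions of this comparison (13320 genes kept), edgeR recovered 50.0% of genes changed 1.5-fold, 84.0% of those changed 2-fold, 93.8% of those changed 4-fold and 100% of those changed 8-fold. It made 10 false calls in 170, and DESeq2 made 33 in 204. With 170 edgeR calls there against 1 in the data, the adjusted threshold was looser in the simulation. The recovery rates therefore overstate recovery in this comparison. In a simulation with 5 lists shifted by 0.5 on the log2 scale and independent genes, fry recovered 5, with 0 false calls among the 31 lists that shared no gene with them. In the data, the members of those 5 lists correlated (estimated correlation 0.33 to 0.62). The simulation therefore does not give fry's recovery or false calls for these data.

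Alternatives were DESeq2 size factors, upper quartile factors, other filters on low counts, the replicate number as a block, limma voom with sample quality weights, a surrogate variable (sva 3.50.0), the DESeq2 1.42.0 Wald test, limma on log2 FPKM, other thresholds, camera and fry's mixed test, and leaving out each tumour in turn. Covariates for the skeletal muscle and cytotoxic scores, the removal of 2 tumours at the ends of the principal components, edgeR's newer quasi-likelihood fit, and the FPKM pseudocount, filter and list test that took the place of TPM ones were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.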

Results

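Bulk mRNA sequencing was carried out on subcutaneous tumours that MC38 cells, a mouse colon cancer line, had formed in male C57 mice. The cells carried TetOn-CXCL14, a construct from which the chemokine CXCL14 is made when the tetracycline analogue doxycycline (DOX) is present. In the induced group the mice drank water with 1 mg/mL DOX for 3 days, and the control group was left uninduced. Each group held 4 tumours from 4 mice. The labels give 300 mm³ both as the tumour size at which DOX was started and as the size at harvest, so the relation between size and treatment time is open. The deposited tables held 18251 genes, and between 18685975 and 19307481 counts per tumour were assigned to them. The comparison of induced with uninduced tumours was designed to ask what CXCL14 does in the tumour microenvironment, and the series' title also names the epithelial-mesenchymal transition. No DOX-treated tumours without the construct are among the samples, so an effect of DOX and an effect of CXCL14 cannot be told apart in any value given here.

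Cxcl14, the induced gene, was 2.61-fold higher in DOX tumours, and every DOX tumour lay above every control tumour. Its expression was 9.34, 9.69, 8.30 and 9.59 CPM (read counts scaled to library size) in control tumours 1 to 4, and 30.1, 30.2, 20.3 and 15.8 CPM in DOX tumours 1 to 4. The group means were 9.23 ± 0.637 and 24.1 ± 7.21 CPM (SD, n = 4 each). Adgrg1, which encodes the adhesion G protein-coupled receptor GPR56, rose 10.4-fold, from 3.24 ± 0.751 to 33.8 ± 5.35 CPM (SD, n = 4 each). The lowest DOX tumour had 7.15 times the Adgrg1 level of the highest control tumour.

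In edgeR's quasi-likelihood test, the log2 fold change of Adgrg1 was 3.38 ± 0.18 (SE), with a Benjamini-Hochberg adjusted p of 6.82e-05 over 13436 tested genes. Adgrg1 was the 1 gene of that test past an adjusted p of 0.05. Cxcl14 ranked 2 by p, with a log2 fold change of 1.38 ± 0.20 (SE) and an adjusted p of 0.387, so it missed that threshold. The exact two-sided permutation test over the 70 allocations of the 8 tumours gave p = 0.0286 for each of the 2 genes, the smallest value these group sizes allow. Any gene whose groups do not overlap gives this value, and 760 genes had no overlap. Adgrg1 was named by a rule that requires this, so for Adgrg1 the exact test adds no support. The Cxcl14 call depended on the test and on DOX tumour 4: its adjusted p was 1.06e-06 with DESeq2 and 0.0166 with edgeR when that tumour was left out, within a range of 1.06e-06 to 0.997 over all alternatives. The species of the CXCL14 sequence in the construct is not stated in the labels, and the level given here is that of the mouse Cxcl14 row.

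**Figure D1:**
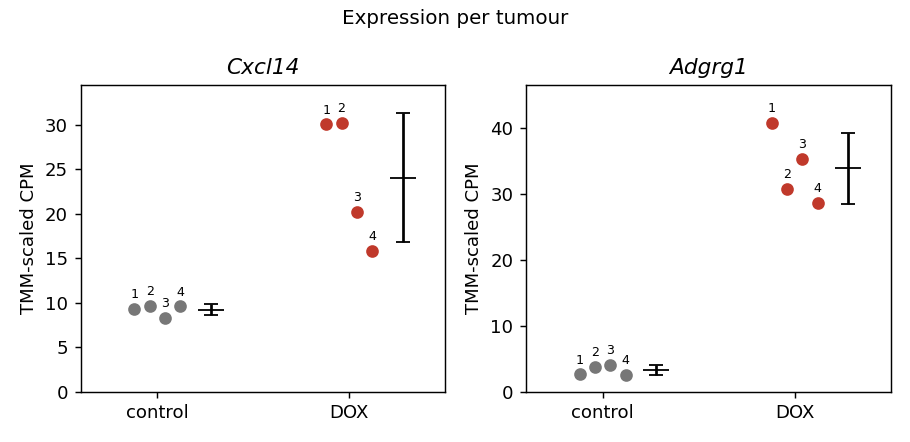
Expression of Cxcl14 (left) and Adgrg1 (right) in each tumour, in CPM scaled by TMM factors, with a linear axis from 0; numbered dots are tumours, and the black marks are the group mean ± SD (n = 4). Every DOX tumour lies above every control tumour for both genes, with means of 24.1 against 9.23 CPM for Cxcl14 and 33.8 against 3.24 CPM for Adgrg1.

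Cxcl14 lies on chromosome 13 (56288643 to 56296811) and Adgrg1 on chromosome 8 (94974756 to 95014208) in GRCm38.p6; the values are gene totals and were not resolved to exons. The genes next to Adgrg1 on chromosome 8 are its family members Adgrg5 and Adgrg3. Their log2 fold changes were 0.80 ± 0.32 and 0.93 ± 0.37 (SE), with adjusted p-values of 0.407 and 0.401, so neither passed. The other tested genes that start within 200 kb of Adgrg1 included the chemokine gene Ccl17, with a log2 fold change of 0.10 ± 0.35 (SE), and the RNA polymerase II subunit gene Polr2c, with 0.05 ± 0.07 (SE). On the short list fixed around Cxcl14, Cxcr4, the receptor of CXCL12, had a log2 fold change of 0.54 ± 0.37 (SE, adjusted p = 0.605). That value rests on DOX tumour 4, with 64.9 CPM against 17.2 to 29.2 in the other DOX tumours and 19.2 to 30.5 in controls. The atypical receptor Ackr3 had -0.07 ± 0.24 (SE, adjusted p = 0.931). Its level was 12.9 CPM in control tumour 1, against 26.9 to 30.5 in the other controls and 21.2 to 28.3 in DOX tumours.

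**Figure D2:**
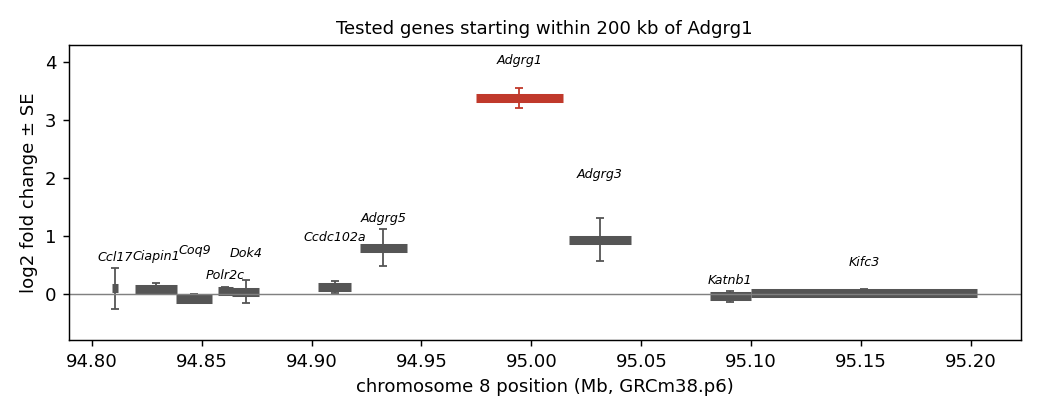
Log2 fold change of DOX over control tumours (vertical axis) against position on chromosome 8 in Mb (GRCm38.p6, horizontal axis) for Adgrg1 and the tested genes that start within 200 kb of it; bars span each gene and whiskers are ± 1 SE. Adgrg1 (red) stands at 3.38, Adgrg3 at 0.93 and Adgrg5 at 0.80, and the others lie near 0.

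In edgeR's test 0 genes fell past the threshold, against 531 with an unadjusted p below 0.05 and 20 called by DESeq2. The 5 genes with the smallest p among those lower in DOX tumours all missed it, each with an adjusted p of 0.387, and in each the DOX tumours lay below all control tumours. Apln, which encodes the vascular peptide apelin, had a log2 fold change of -0.62 ± 0.12 (SE), from 26.6 ± 3.58 to 17.3 ± 1.77 CPM (SD, n = 4 each). Dkk2, a secreted modulator of Wnt signalling, had -0.60 ± 0.13 (SE), and the Krüppel-like transcription factor gene Klf11 had -0.69 ± 0.15 (SE). Ptchd1, a patched-domain membrane protein gene, had -0.70 ± 0.15 (SE). The protocadherin gene Pcdhga1 had -1.14 ± 0.21 (SE), at 3.79 ± 0.495 CPM in control and 1.71 ± 0.377 CPM in DOX tumours (SD, n = 4 each). Pcdhga1 shares its 3' exons with the other genes of the gamma cluster and had a whole-number count in 0 of 8 libraries, so its level is uncertain. Dkk2 and Ptchd1 had whole-number counts in 0 of 8 libraries and Klf11 in 3 of 8, so their levels also hold shared reads; Apln had them in 8 of 8.

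Without correction, 1559 genes (11.6% of those tested) had p below 0.05, of which 1028 were higher and 531 lower in DOX tumours. The groups did not overlap in 760 genes, or 5.66%, where chance gives 2.86%. DESeq2 called 79 genes at an adjusted p of 0.05, with 59 higher and 20 lower. Of those 79, 59 had groups that did not overlap. DESeq2 was run on all 18251 genes, without edgeR's filter. Its calls Sfrp1, Pakap, Smyd1 and Ddn were not tested by edgeR, and their overlap was not assessed. Members of the gene lists fixed before the data were examined made up 30 of the higher and 8 of the lower DESeq2 genes. These included the cytotoxic T cell gene Cd8b1, the complement gene C3 and the chemokine gene Ccl8 on the higher side, and the hypoxia-induced genes Ddit4 and Kdm3a on the lower side.

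The T cell list was on the higher side in DOX tumours, with a median log2 fold change of 1.21 (limma fry adjusted p = 0.179). Adjusted over the list alone, 21 of its 23 tested members rose and 0 fell; over all genes tested, 0 passed with edgeR and 5 with DESeq2. The T cell receptor component gene Cd3d stood at 2.18 ± 0.926 CPM in control and 7.49 ± 4.97 CPM in DOX tumours (SD, n = 4 each), with a whole-number count in 0 of 8 libraries. The T cell receptor kinase gene Zap70 had a log2 fold change of 1.35 ± 0.33 (SE), and the signalling regulator Ubash3a 1.40 ± 0.37 (SE). The exception in sign was Lef1, a transcription factor gene that tumour cells can also express, with -0.29 ± 0.15 (SE). The list score, the mean log2 CPM of the members, was 1.85 ± 0.23 in control and 2.89 ± 0.64 in DOX tumours (SD, n = 4 each). All 4 DOX tumours lay above all controls, but narrowly, with 2.20 in DOX tumour 1 against 2.15 in control tumour 3. The exact permutation p was 0.0286, the smallest value these group sizes allow, which any list without overlap gives. Exact p-values of list scores, here and below, were not adjusted over the lists, so this value adds little to the fry result. Within the DOX group the T cell score did not rise with Cxcl14. It was 2.20, 2.85, 2.77 and 3.75 in DOX tumours 1 to 4, where Cxcl14 stood at 30.1, 30.2, 20.3 and 15.8 CPM.

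The list of CD8 T cell and cytotoxic genes had a median of 1.13 (fry adjusted p = 0.179), and 17 of its 26 members rose when adjusted over the list alone. Cd8b1, the beta chain of the CD8 co-receptor, went from a mean of 8.18 ± 2.05 CPM in control to 22.3 ± 11.4 CPM in DOX tumours (SD, n = 4 each), and its count was likewise whole in 0 of 8 libraries. The granule protein gene Nkg7 had a log2 fold change of 1.23 ± 0.34 (SE), the killer lectin-like receptor gene Klrd1 1.16 ± 0.32 (SE) and the chemokine receptor gene Cxcr6 1.58 ± 0.44 (SE). DOX tumour 4 was highest in Nkg7 and Klrd1, at 48.3 and 25.9 CPM, against 14.6 to 23.3 and 9.06 to 12.2 CPM in the other DOX tumours. The natural killer cell list, which shares Nkg7 and Klrd1 with the CD8 T and cytotoxic list, had a median of 0.48 (fry adjusted p = 0.179). Of its 24 members 8 rose over the list alone, among them the interleukin receptor gene Il2rb at 0.97 ± 0.26 (SE). The natural killer cell receptor genes Ncr1 and Klrb1c, chosen after their values were seen, were not among the 8. They had 0.46 ± 0.29 and 0.15 ± 0.21 (SE). The regulatory T cell list had a median of 0.86 (fry adjusted p = 0.179) with 2 of 10 risen. These 2 were Ccr8, with 1.43 ± 0.41 (SE), and Tnfrsf9, with 0.95 ± 0.28 (SE). Ccr8 was low, at 0.447 ± 0.186 CPM in control and 1.22 ± 0.541 CPM in DOX tumours (SD, n = 4 each). Tnfrsf9 overlapped between the groups, with 14.6 CPM in control tumour 1 and 14.5 CPM in DOX tumour 1. The lineage transcription factor gene Foxp3 had 1.08 ± 0.40 (SE) and was not among the 2 risen members. The immune checkpoint list had a median of 0.65 (fry adjusted p = 0.221); 0 of its 25 members passed over the list alone, although 14 had an unadjusted p below 0.05 and DESeq2 called 2. Among its members the inhibitory receptor gene Lag3 had 1.34 ± 0.40 (SE) and the co-stimulatory receptor gene Icos 1.70 ± 0.50 (SE), or 1.10 without DOX tumour 4.

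The lists of antigen presentation through MHC class II and of macrophages were also on the higher side (fry adjusted p = 0.179 for each). The MHC class II list had a median of 0.76, and 13 of its 15 tested members rose when adjusted over the list alone. Ciita, the master regulator of these genes, stood at 36.3 ± 6.63 CPM in control and 63.3 ± 15.5 CPM in DOX tumours (SD, n = 4 each). H2-DMb1 and H2-DMa, whose products load peptides onto class II molecules, had log2 fold changes of 0.76 ± 0.17 and 0.77 ± 0.21 (SE), and H2-Oa 1.32 ± 0.35 (SE). The macrophage list had a median of 0.49 with 13 of 27 members risen over the list alone. Csf1r, the receptor of the macrophage growth factor CSF1, had 0.47 ± 0.12 (SE). The C1q genes C1qa, C1qb and C1qc had 0.65 ± 0.16, 0.73 ± 0.18 and 0.68 ± 0.17 (SE). C1qa stood at 577 ± 54.1 CPM in control and 909 ± 230 CPM in DOX tumours (SD, n = 4 each). The dendritic cell list had a median of 0.39 (fry adjusted p = 0.179) and 0 of 23 members passed over the list alone, with 9 at an unadjusted p below 0.05 and 0 called by DESeq2. The integrin gene Itgax was among them at 0.78 ± 0.24 (SE).

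The chemokine list had a median of 0.58 (fry adjusted p = 0.190), and 2 of 23 members rose when adjusted over the list alone. Ccl8, a chemokine that attracts monocytes, had a mean of 44.0 ± 16.2 CPM in control and 194 ± 132 CPM in DOX tumours (SD, n = 4 each), and Ccl1, the ligand of CCR8, had a log2 fold change of 1.76 ± 0.38 (SE). The chemokine receptor list had a median of 0.51 (fry adjusted p = 0.179) with 2 of 14 risen; besides Ccr8 and Cxcr6, the lymph node homing receptor gene Ccr7 had 1.21 ± 0.45 (SE). The complement and coagulation list had a median of 0.36 (fry adjusted p = 0.209) with 7 of 24 risen. C3, the central complement component, had 1.79 ± 0.39 (SE), from 94.9 ± 22.9 to 328 ± 194 CPM (SD, n = 4 each).

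In the directional fry test of limma, which asks whether a list's genes move one way on balance, none of the 49 tested lists passed an adjusted p of 0.05, and the smallest was 0.179. Without correction 11 lists had p below 0.05, with 10 up and 1 down. Camera with a preset correlation of 0.01 called 27 lists, none of which held with an estimated correlation (smallest adjusted p = 0.354), and fry's mixed test called 1 list, plasma cell. When DOX tumour 1 was left out, 10 lists passed the directional test: T cell, CD8 T and cytotoxic, regulatory T cell, immune checkpoint, dendritic cell, macrophage, chemokine, chemokine receptor, MHC class II and complement. Lists share members, so these do not count as 10 separate results. Of the tested members, 13 of 26 in the CD8 T and cytotoxic list and 14 of 27 in the macrophage list were also in another list. DOX tumour 1 lay with the controls on the first principal component (-10.5, against -27.3 to -9.35 in controls and 14.9 to 43.1 in the other DOX tumours), so its removal sets aside the DOX tumour most like them. Without DOX tumour 4, the median of the CD8 T and cytotoxic list was 0.70 in place of 1.13. The score of skeletal muscle genes, markers of another tissue, was higher in DOX tumours along with these lists (2.43 ± 0.98 against 0.53 ± 1.35, SD, n = 4 each).

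**Figure D3:**
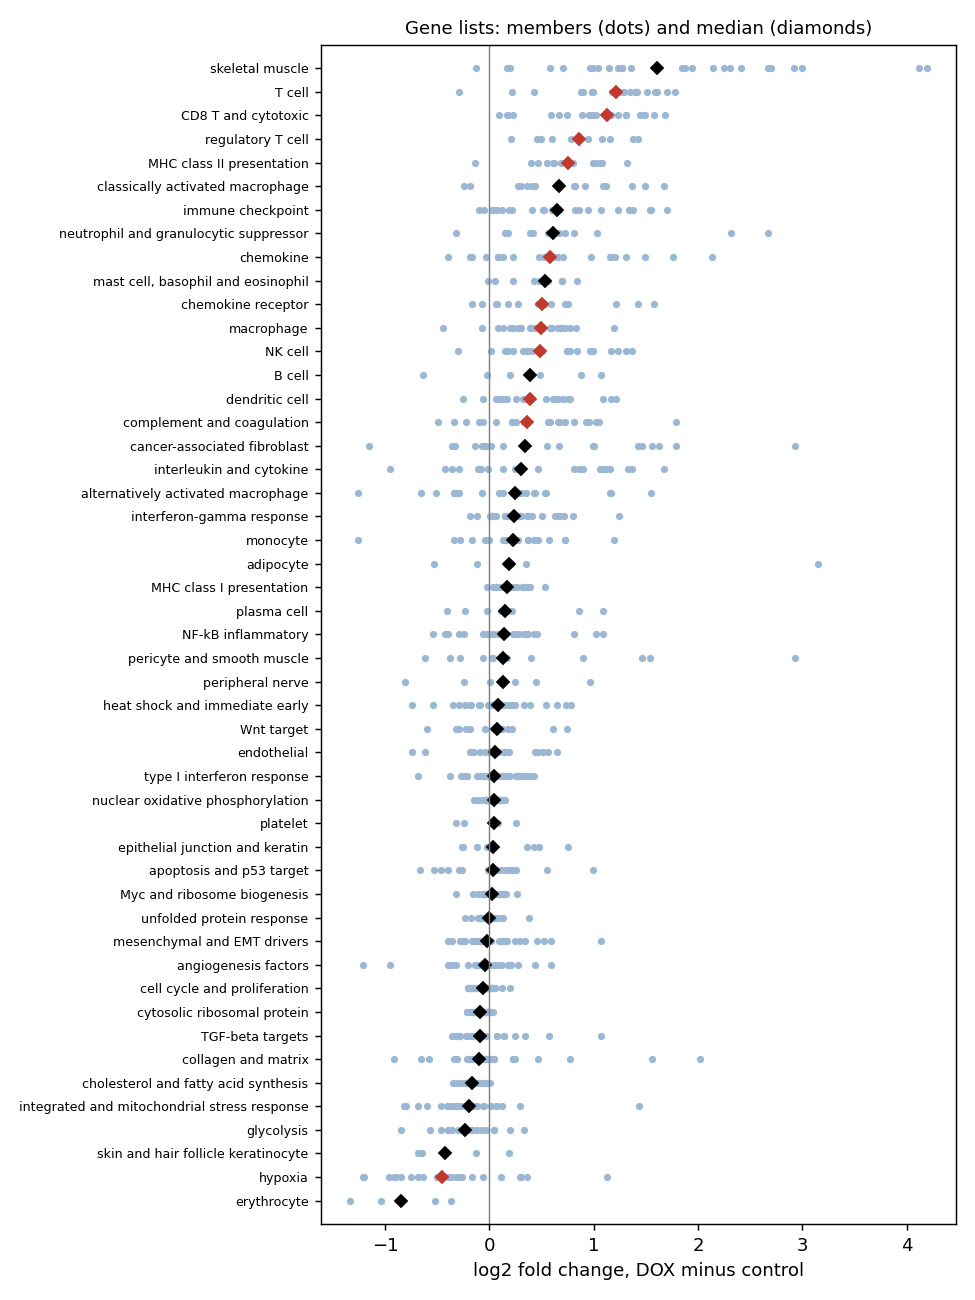
Log2 fold change of DOX over control tumours (horizontal axis) for the tested members (blue dots) and the median (diamonds) of the 49 gene lists (rows); red diamonds mark the 11 lists with an unadjusted fry p below 0.05, none of which passed after adjustment. The median was 1.21 for T cell genes, 1.13 for CD8 T and cytotoxic genes and -0.45 for hypoxia genes.

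The hypoxia list was on the lower side in DOX tumours, with a median of -0.45 and a fry adjusted p of 0.209. Adjusted over the list alone, 17 of its 29 tested members fell and 1 rose. Over all genes tested, 0 passed with edgeR and 6 with DESeq2. The hypoxia score was 7.14, 7.06, 6.66 and 6.55 in control tumours 1 to 4, against 6.33 to 6.62 in DOX tumours (exact permutation p = 0.0571). The median was -0.33 without control tumour 1 and -0.53 without control tumour 4. The histone demethylase gene Kdm3a, which was among the 17, stood at 212 ± 25.9 CPM in control and 136 ± 28.4 CPM in DOX tumours (SD, n = 4 each). Ddit4, an inhibitor of mTOR signalling, had a log2 fold change of -0.96 ± 0.24 (SE), and the mitophagy receptor gene Bnip3l had -0.46 ± 0.12 (SE). Of the 5 members on the higher side, the 1 that rose over the list alone was Slc2a3, a glucose transporter gene that leukocytes also express, with 1.12 on the log2 scale; it was chosen after its value was seen. The glycolysis list, which shares members with the hypoxia list, had a median of -0.23 and a fry adjusted p of 0.461. Its score was 8.11, 7.98, 7.67 and 7.57 in control tumours 1 to 4, against 7.54 to 7.72 in DOX tumours. In it 0 of 21 members passed over the list alone with 9 at an unadjusted p below 0.05, and DESeq2 called 0. Pgk1, a glycolytic kinase gene, had -0.47 ± 0.13 (SE) and the glucose transporter gene Slc2a1 -0.85 ± 0.27 (SE). In the angiogenesis list, with a median of -0.04 and a fry adjusted p of 0.584, the peptide hormone gene Adm, itself hypoxia-induced, had -1.21 ± 0.33 (SE). The Adm level was 24.7, 24.7, 8.67 and 13.5 CPM in control tumours 1 to 4, against 6.28 to 9.63 CPM in DOX tumours.

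No movement of epithelial-mesenchymal transition genes in one direction passed the test. The list of mesenchymal genes and transition drivers had a median of -0.03, a mean of 0.05 and an upward fry direction, so the signs differ, and its fry adjusted p was 0.867. Of its 35 tested members, 0 passed over the list alone with edgeR, 1 had an unadjusted p below 0.05 and 0 were called by DESeq2. That member was Tgfb1, with a log2 fold change of 0.25 ± 0.09 (SE). The receptor kinase gene Axl had 0.13 ± 0.06 (SE). Of the classic markers, chosen after their values were seen, the intermediate filament gene Vim had -0.05 ± 0.08 (SE) at 3104 ± 226 CPM in control and 2996 ± 239 CPM in DOX tumours (SD, n = 4 each), and the transcription factor genes Zeb1, Snai1 and Twist1 had -0.16 ± 0.10, -0.23 ± 0.16 and -0.01 ± 0.08 (SE). The epithelial cadherin gene Cdh1 had -0.25 ± 0.47 (SE), a sign that rests on control tumour 1, with 19.8 CPM against 4.77 to 5.15 CPM in the other controls and 6.05 to 8.62 CPM in DOX tumours. The epithelial junction and keratin list, of which only 9 of 34 genes were tested, had a median of 0.04 and a fry adjusted p of 0.525. The TGF-beta target list had a median of -0.09 (fry adjusted p = 0.673), and the Wnt target list a median of 0.07 with a downward fry direction (adjusted p = 0.957); Dkk2 was its 1 member that fell when adjusted over the list alone.

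The stromal and vascular lists did not pass the directional test either. The endothelial list had a median of 0.05 (fry adjusted p = 0.867), and 1 of its 25 members, Apln, fell when adjusted over the list alone. The endothelial co-receptor gene Eng had a log2 fold change of 0.51 ± 0.17 (SE). The collagen and matrix list had a median of -0.10, a mean of 0.03 and a fry adjusted p of 0.803. Its members pointed both ways, with the elastic fibre gene Fbln5 at -0.58 ± 0.20 (SE) and Fbln2 at 2.02 ± 0.72 (SE). The Fbln2 value was 1.15 without DOX tumour 2 and 2.61 without control tumour 2. The fibroblast list had a median of 0.34 and a fry adjusted p of 0.561; 3 of its 20 members rose over the list alone, among them C3, Thy1 at 1.00 ± 0.27 (SE) and the growth factor gene Igf1 at 1.43 ± 0.39 (SE). Thy1 is also a T cell gene, and C3 is also made by macrophages. The pericyte and smooth muscle list had a median of 0.13 (fry adjusted p = 0.757), and its smooth muscle actin gene Acta2 had 1.46 ± 0.57 (SE). The Acta2 level was 5.64, 39.6, 9.92 and 25.4 CPM in DOX tumours 1 to 4, against 4.72 to 10.2 CPM in controls.

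**Figure D4:**
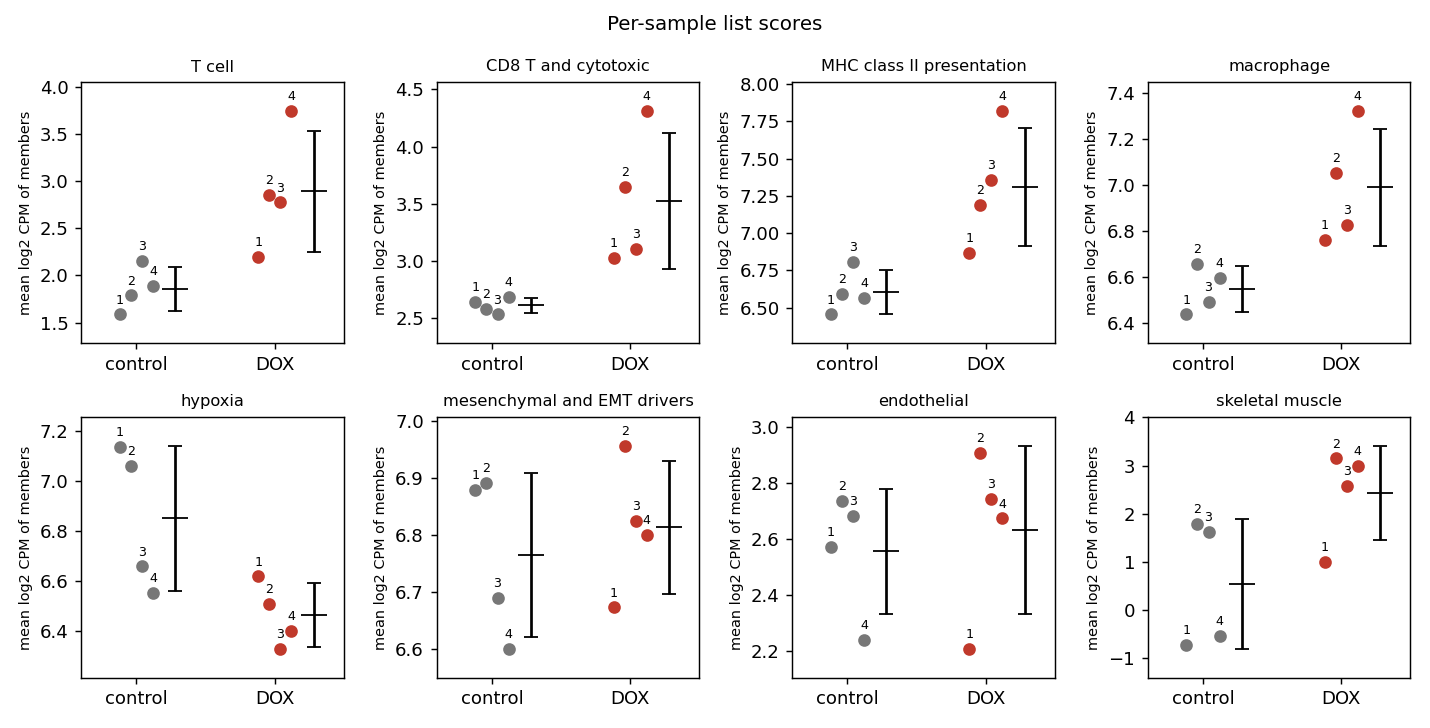
Per-tumour scores of 8 gene lists, each the mean log2 CPM of the list's tested members (vertical axis, log2 scale, not starting at 0); numbered dots are tumours and black marks the group mean ± SD (n = 4). All 4 DOX tumours lie above all controls for T cell, CD8 T and cytotoxic, MHC class II and macrophage genes, and 3 of 4 lie below all controls for hypoxia genes; the scores of mesenchymal and endothelial genes overlap.

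Skeletal muscle genes, by their list score, were higher in 3 of the 4 DOX tumours than in any control. The muscle list had a median of 1.60, the highest of all lists. Its fry adjusted p was 0.221, 0 of 30 members passed over the list alone, 16 had an unadjusted p below 0.05 and DESeq2 called 0. Its score was 0.53 ± 1.35 in control and 2.43 ± 0.98 in DOX tumours (SD, n = 4 each), with an exact permutation p of 0.0857. The muscle creatine kinase gene Ckm had a log2 fold change of 4.19 ± 1.20 (SE), or 3.54 without DOX tumour 4, and the fast myosin gene Myh4, chosen after its values were seen, stood at 1.21 ± 1.40 CPM in control and 21.3 ± 21.5 CPM in DOX tumours (SD, n = 4 each), with 0.880, 35.3, 5.01 and 43.9 CPM in DOX tumours 1 to 4. With the muscle score as a covariate, a setting added after the data were examined, the T cell median was 0.66 in place of 1.21 and the MHC class II median 0.49 in place of 0.76.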

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

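In each group of 4 tumours, values were screened for a tumour far from the other 3, by the gap to its nearest neighbour as a share of the group's range. Of 114 groups of values screened, 5 passed the 95% critical value of 0.829, where chance gives about 5.7, so such gaps were no more frequent than by chance. The groups share tumours and list members, so this count cannot assign any single gap to chance. No explanation was tested for them.

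Among the named genes, Apln in DOX tumour 3 stood apart with a gap of 0.934 of the range, at a log2 CPM of 3.88 against 4.18 to 4.20 in the other DOX tumours. Control tumour 1 stood apart in 3 list scores, and also on the second principal component (38.4, against -15.6 to 13.1 in the other tumours). Its score was 6.73 for integrated and mitochondrial stress response genes against 6.01 to 6.11 in the other controls (gap 0.863), 5.27 for monocyte genes against 4.63 to 4.72 (gap 0.860), and 5.83 for NF-kB inflammatory genes against 5.28 to 5.34 (gap 0.890). DOX tumour 1 had a score of 7.37 for unfolded protein response genes, against 7.24 to 7.26 in the other DOX tumours (gap 0.881).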

How the results depend on the processing

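The settings planned before the data were examined are compared first; covariates, the removal of 2 tumours together, 1 edgeR option and the FPKM pseudocount and filter were chosen after the data were seen. Adgrg1 passed the threshold under every gene-level alternative run, with log2 fold changes of 2.46 to 3.71. Cxcl14 stayed on the higher side in all of them (1.20 to 1.77). With the DESeq2 Wald test 79 genes passed (59 higher, 20 lower), with Cxcl14 at 1.38 among them, and at an unadjusted p below 0.05 with an absolute log2 fold change of at least 1 there were 217 (205 higher, 12 lower). The cause of the difference between DESeq2 and edgeR was not tested, though DESeq2 also made more false calls on simulated counts. Camera with the preset correlation called 27 lists and fry's mixed test 1; these ask other questions than the directional test, and camera with an estimated correlation called 0.

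Leaving out each tumour in turn gave 1 to 2 genes, with 1 to 2 higher and 0 lower, and 0 to 10 lists; Cxcl14 ranged from 1.26 to 1.54. The 2 genes came without DOX tumour 4, when Cxcl14 passed, and the 10 lists without DOX tumour 1. The T cell median lay between 0.88 (without DOX tumour 4) and 1.45 (without DOX tumour 1). Without control tumour 1 and DOX tumour 4 together, the gene count was 1, the list count 0 and the T cell median 0.78.

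With the tumour number as a replicate block, 1 gene and 0 lists passed, as without it, and Cxcl14 had a log2 fold change of 1.34 (edgeR adjusted p = 0.115). Deviations of same-numbered tumours correlated across genes at 0.00, 0.04, 0.09 and -0.02, within the range of -0.20 to 0.22 for tumours of different numbers. These values show no pairing by number, but so few pairs cannot exclude one.

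The 1 call of edgeR, Adgrg1, was neither lost nor reversed. The directional fry test made 0 calls in the main setting, so it had none to lose. A value passed under an alternative that had not in the main test in 13 cases given above and 71 others. Among genes and lists not called by these 2 tests, up to 60 genes (cytotoxic covariate) and 9 lists (muscle covariate) changed sign; some of these lists, such as skeletal muscle, had been called by camera with the preset correlation. The tests on TPM that had been foreseen were not run, since no TPM column could be given a sample, and FPKM took their place. At this depth and group size, 50% of simulated 1.5-fold changes were recovered, and smaller changes were not simulated. With 170 genes called in the simulation against 1 in the data, its adjusted threshold was looser, so that rate overstates recovery here.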

Other observations

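Besides the groups described, B cell, granulocyte and cytokine lists were mostly on the higher side in DOX tumours, and none passed fry's directional test after adjustment. The B cell list, of which only 7 of 25 genes were tested, had a median log2 fold change of 0.39 (fry adjusted p = 0.438). Its inhibitory B cell receptor gene Cd22 had 1.07 ± 0.36 (SE). Its member Fcer2a went the other way, with -0.64 ± 0.26 (SE) and all DOX tumours below all controls. Fcer2a had a whole-number count in 0 of 8 libraries. The plasma cell list had 0.15 (0.761), with the transcription factor gene Irf4 at 1.09 ± 0.31 (SE) and Eaf2 at -0.41 ± 0.11 (SE). The mixed test called the plasma cell list alone (adjusted p = 0.0376), and its members went both ways, 1 up and 1 down when adjusted over the list alone. Neutrophil genes had a median of 0.62 (0.336), or 0.21 without DOX tumour 4, with the myeloid lectin receptor gene Clec4d at 2.68 ± 0.81 (SE), or 1.65 without that tumour; its level in DOX tumour 1, 2.95 CPM, lay below every control (3.68 to 4.92 CPM). Mast cell, basophil and eosinophil genes had 0.53 (0.360) and monocyte genes 0.22 (0.461), with the lysozyme gene Lyz2 at 1.20 ± 0.32 (SE). The list of classically activated macrophage genes had a median of 0.67 (0.335), with 2 of 17 members risen over the list alone. The cytokine gene Tnf had 1.09 ± 0.27 (SE) and Il12b, a subunit of interleukin-12, 1.68 ± 0.44 (SE). The alternatively activated list had 0.25 (0.561), interleukins and cytokines 0.30 (0.328) and NF-kB inflammatory genes 0.14 (0.561). Interferon-gamma response genes had a median of 0.24 (0.561), or 0.67 without control tumour 1, and type I interferon response genes 0.05 (0.803). The type I score was 6.53 in control tumour 1, against 5.46 to 5.81 in the other controls and 5.73 to 6.24 in DOX tumours. MHC class I genes had 0.17 (0.438), with H2-D1 at 0.39 ± 0.14 (SE). Reads of H2-D1 and H2-K1 can be shared between class I genes.

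Growth and housekeeping lists lay near 0. The medians, with the fry adjusted p in parentheses, were -0.06 for cell cycle genes (0.561), 0.03 for Myc and ribosome biogenesis (0.867), -0.09 for cytosolic ribosomal proteins (0.584), 0.04 for nuclear oxidative phosphorylation (0.749), 0.04 for apoptosis and p53 targets (0.803), 0.00 for the unfolded protein response (0.957) and 0.08 for heat shock and immediate early genes (0.757). Integrated and mitochondrial stress genes had -0.19 (0.584) and cholesterol and fatty acid synthesis genes -0.16 (0.623). The stress score was 6.73 in control tumour 1, against 6.01 to 6.11 in the other controls and 5.97 to 6.18 in DOX tumours. Of the lists for other tissues and blood, adipocyte genes had 0.19 (0.503), keratinocyte genes -0.42 (0.335), nerve genes 0.13 (0.749), erythrocyte genes -0.85 (0.561), or -0.30 without control tumour 1, and platelet genes 0.04, with a mean of -0.04 (0.867).

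The tests in the rest of this part were chosen before the tested result was seen, except those on cytotoxic cells, on the neighbours of Adgrg1, on stromal scores, on macrophage against Y-linked genes, on the T cell score minus the Y-linked score in each tumour and on splits by unadjusted lists. The muscle covariate was a setting added after the data were examined, with its test fixed before its own result was seen.

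Adgrg1 rose in all 4 DOX tumours. Its log2 fold change was 3.71 (edgeR adjusted p = 9.37e-05) with the cytotoxic score as a covariate, which argues against cytotoxic lymphocytes, which can express this gene, as the whole source. A gain of the whole region within 200 kb is argued against by a median log2 fold change of 0.070 (median absolute deviation 0.0832) over its tested neighbours. The genes next to Adgrg1, Adgrg5 (0.80 ± 0.32, SE) and Adgrg3 (0.93 ± 0.37, SE), were on the higher side without passing. The median therefore cannot decide on a change confined to them. Whole-number counts in 6 of 8 libraries argue against reads shared with a paralog. A response to DOX itself, to CXCL14, or to a construct inserted beside Adgrg1 in the injected cells stays open, since no DOX-treated tumours without the construct and no junction reads were analysed here, so a biological source is a hypothesis only.

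The higher T cell and MHC class II lists may come from more immune cells per tumour or from a lower share of tumour cells, which would raise every host cell type. The T cell score minus the endothelial score was higher in DOX tumours by 0.96 (exact permutation p = 0.0286, adjusted p = 0.229 over 12 such differences), but the largest p over the 3 stromal lists was 0.143, so a lower tumour share cannot be told apart from them. Y-linked genes, which male host cells carry, had a median of 0.55 against 1.21 for T cell genes; that gap exceeds the standard error of the T cell median over genes (0.0901), but this error treats members as independent although they correlate (0.55), and over tumours the difference of scores gave an exact permutation p of 0.0571, so this too stays open. It assumes that MC38 cells carry little Y-linked RNA, which the labels do not state. Muscle in the sampled tissue also stays open: with its score as a covariate the T cell median was 0.66 with a fry p of 0.210.

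The macrophage list lay -0.053 from the Y-linked median on the log2 scale (standard error 0.0638), but this error also treats correlated members as independent. A larger share of host cells would raise stromal genes too, and the endothelial median was 0.05; the macrophage score minus the endothelial score was higher in DOX tumours by 0.37 (exact permutation p = 0.114). Its differences from the pericyte and fibroblast scores were 0.01 (exact permutation p = 0.914) and -0.05 (exact permutation p = 0.829). Whether a larger host share lies behind the macrophage list therefore stays open. Of the Y-linked genes, Ddx3y had a mean of 11.3 CPM in control and 17.8 CPM in DOX tumours, and its X-linked partner Ddx3x 422 and 402 CPM. Uty had a log2 fold change of 0.14 ± 0.11 (SE).

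Chance was not excluded for the count of genes or of lists at an unadjusted p below 0.05. Of the 35 splits of the 8 tumours into 4 and 4, 3 gave at least the 1 gene of the real split (highest other, 3) and 2 gave at least its 11 lists at an unadjusted p below 0.05 (highest other, 19). For lists past the adjusted threshold the comparison decides nothing, because the real split gave 0 and all 35 splits must give at least that (highest other, 7). The split with 3 genes, 7 lists and 19 unadjusted lists set control tumour 1 with DOX tumours 2 to 4 against the rest. It was picked as the highest of the 35. It keeps DOX tumours 2 to 4 together and exchanges control tumour 1 with DOX tumour 1, so it shares part of the treatment contrast. In the interferon-gamma response score, control tumour 1 (7.83) lay with DOX tumours 2 to 4 (7.41 to 7.79). DOX tumour 1 (6.93) lay with control tumours 2 to 4 (6.63 to 6.90). The monocyte scores divided the same way, at 5.11 to 5.50 against 4.56 to 4.72. In the T cell score, by contrast, control tumour 1 was the lowest, at 1.59. By chi-square per degree of freedom, DOX tumour 1 was closer to control tumours 3 (5.25, the lowest of the 28 pairs) and 2 (10.1) than to any DOX tumour (11.3 to 49.4). Control tumour 1 was far from all 7 others (31.7 to 71.7), and no closer to DOX tumours 2 to 4 (38.7, 37.9 and 71.7) than to the other controls (34.1 to 37.0).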
